A study of Mus musculus with 31 samples.

How the data were processed

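RNA of 31 BXD recombinant inbred mouse strains was measured on spotted glass arrays carrying 23040 probes, with 1 array per strain. Each BXD strain is inbred and descends from a cross of C57BL/6J and DBA/2J, so it is fixed at each locus for the allele of either parent. Per the labels, equal amounts of RNA from 3 male mice aged 8 weeks were pooled for each strain, labelled with a red dye and hybridized against a common C57BL/6J reference labelled with a green dye. The dyes were not swapped on any array, and spike-in transcripts were added to the reference. Sample titles name kidney while the source fields name whole brain, and the labels do not settle which tissue was used.

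The deposited values are log2 ratios of strain to reference, as far as the labels and the values allow. The labels name R 2.0.0 and limma as the authors' tools and give neither the steps nor the base and direction of the logarithm. Strain over reference in log2 is the likely reading, from the red over green convention of limma. Genes with known parental differences, given with the results, do not settle it. The sorted values were identical in all 31 columns, with a median of 0.0127, an SD of 0.602 and no missing value, so the authors had made the arrays alike by quantile normalization. Signal intensities and the scanner files were not used here, so signal over background is unknown. The number of arrays limits the precision.

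Probes carried the gene names of the deposited platform table. A single gene name was given for 16874 probes, several for 134 and none for 6032, and the names covered 15096 genes. Of the named probes, 16196 were matched by gene number to the RefSeq gene table of assembly GRCm38.p6, which served only for gene names and for the order of genes along chromosomes. For gene lists and neighbouring genes, the probes of a gene were averaged.

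Strains were placed in the groups BXD1-32 (24 arrays) and BXD33-42 (7 arrays). The division follows background knowledge of an earlier and a later breeding of the panel and is not in the labels. Each strain had 1 array of pooled RNA and the reference had no spread of its own. P-values thus measure the spread between the arrays of strains, in which strain and array effects cannot be told apart. The limma fits treated the arrays as independent.

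The comparisons, gene lists, rule for naming genes and first alternatives were fixed before the data were examined. The mean log2 ratio of each probe over the 31 strains was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided). BXD33-42 were compared with BXD1-32 with the same functions. P-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. Strain values in 2 clusters were sought per probe as the share of the sum of squares over strains removed by the best split with at least 5 strains on each side. This share was set against 100000 simulated normal samples in a 1-sided test.

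A total of 35 gene lists covered kidney cell types, other cell types and tissues, metabolic and cellular processes, genes known to differ between the parents, and sex-chromosome genes. At least 5 genes were measured for 29 of them, which were tested. Camera, with a preset correlation of 0.01, compared each list with all other genes. Alternatives were camera with an estimated correlation and fry, a self-contained test of whether the genes of a list moved on balance in 1 direction. Covariation of a list was the mean pairwise Pearson correlation of its genes over strains, against 10000 random lists of the same number of genes in a 1-sided permutation test. Counts of list members past the threshold are given over all genes and adjusted over the list alone. Neighbouring genes were compared by the mean absolute correlation of adjacent measured genes, against 1000 shuffles of the genes over their positions. Single adjacent pairs were set against the pooled correlations of shuffled pairs and adjusted over all pairs.

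Genes were named by rule. For the panel mean, these were the 12 highest and 12 lowest probes with 1 gene name, past the threshold and of the same sign in at least 28 strains. For 2 clusters they were the 24 probes with the largest distance of cluster medians, and for neighbours the 10 adjacent pairs of largest absolute correlation. For BXD33-42 against BXD1-32, fewer than 5 probes with 1 gene name passed, so the rule named the 5 with the smallest p. In each called list, up to 4 members of largest correlation with the list or largest difference were named, as were all measured genes known to differ between the parents, those with mutations that arose after the first set, and sex-chromosome genes.

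Alternatives fixed at the start were centring each array on its median, repeating the quantile normalization, leaving out the 10% of probes with the smallest spread, array weights, robust eBayes, treat with a log2 change of 0.2, the first principal component removed or added as a covariate, a null from a t distribution with 5 degrees of freedom, at least 3 strains a side, the dip statistic, Spearman correlation, the probe with the largest spread, pairs without gene families, and leaving out each strain in turn. Added after seeing the data were removal of spot position, removal of 3 principal components or of the means of 6 array clusters, fits within array clusters of at least 6 arrays, leaving out BXD15 and BXD38, 5000000 simulated samples, alone and with components or cluster means removed, and 10 other sets of random numbers. Array clusters came from average linkage on 1 minus the correlation between arrays. Spot position was inferred from a repeat of 480 spots in the values, with 48 spots sharing each position.

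The steps were tested on simulated data of 23040 probes. Of 100 probes given a mean of 0.5, 92% were recovered, and of 100 given a mean of 1, 100%. For BXD33-42 against BXD1-32 the shares were 23% and 77% for differences of 0.5 and 1. For 2 clusters they were 37% and 98% for clusters 4 and 6 SD apart, 19% and 75% with the first principal component removed, and 1% and 25% with 3 components removed. The first component of the data was added to the simulated values before removal of 1 component. Nothing was added before removal of 3, so those shares come from values without the structure of the arrays. Calculations outside R used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.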

Results

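Transcript levels were measured in 31 BXD strains against C57BL/6J, 24 of them from BXD1-32 and 7 from BXD33-42, with 1 array of RNA pooled from 3 mice for each strain. Every array had 23040 log2 ratios with a range of -4.07 to 4.95. Titles of the samples named kidney and source fields named whole brain. Correlations between arrays ran from -0.0926 to 0.808 with a median of 0.363, and the first 3 principal components held 20.6%, 11.3% and 9.34% of the variance. The arrays were cut into 6 clusters, a number set in the analysis. Clusters 1, 4 and 5 held 10, 6 and 9 arrays, of which 1, 3 and 2 were of BXD33-42. Cluster 2 held 4 arrays, all of BXD1-32, while BXD15 and BXD38 stood alone. The clusters thus overlap in part with the breeding groups and with strain order. All arrays from BXD1 to BXD14 were in clusters 1 and 2, and clusters 4 and 5 held only strains from BXD16 on. The cause of this order was not tested. Gapdh, a glycolytic gene spotted 232 times, had an SD among its spots of 0.370 to 0.987 within an array. For 884 genes with 2 different probes, the median correlation of the probes over strains was 0.0196, against -0.000548 for random pairs. A correlation over 0.5 was reached by 3.85% of these pairs and 2.6% of random pairs. Probes of 1 gene thus hardly agreed over strains. Whether noise, wrong gene names or real differences between probes cause this was not tested. Values of single probes are given under gene names but are not measures of the gene as a whole.

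The first comparison asked which transcripts differed on average between the BXD strains and C57BL/6J. Tuba1b, which encodes an alpha-tubulin, had the highest mean log2 ratio of the genes named by rule, 1.43 ± 0.187 (SE, n = 31 strains, adjusted p = 8.99e-08), and was above 0 in 31 of 31 strains. The ribosomal stalk gene Rplp1 (1.25 ± 0.124), the heparan sulfate polymerase gene Ext2 (1.25 ± 0.130), the oocyte kinase gene Mos (1.19 ± 0.0979) and Tmem176a (1.17 ± 0.175) were each higher in 30 of 31 strains. Hao2, which encodes a peroxisomal hydroxyacid oxidase, was higher in 31 of 31 strains at 1.18 ± 0.143. At the other end, Tex46 fell to -1.81 ± 0.157 (adjusted p = 2.82e-11) and the interferon-inducible gene Ifi204 to -1.68 ± 0.154. Nrap, which encodes a muscle anchoring protein, was below 0 in every strain at -1.64 ± 0.134 (adjusted p = 7.64e-12). So was Tcirg1, which encodes a subunit of the vacuolar proton pump, at -1.49 ± 0.109 (adjusted p = 8.89e-13). Antxr2, an anthrax toxin receptor gene, stood at -1.63 ± 0.124, and the nuclear noncoding RNA Malat1 at -1.48.

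The other genes named on the high side were Trbv3 (1.37), 2900060B14Rik (1.30), Llgl2 (1.29), Ankrd40 (1.29), Ms4a6c (1.28) and Lrr1 (1.18). Those on the low side were 4930552P06Rik (-1.60), Rad54l2 (-1.54), Rab3gap1 (-1.51), Ccdc71 (-1.42), Fam122b (-1.42) and Pfdn5 (-1.41). Second probes did not always give these values: Ankrd40 had probes at -0.06 and 1.29, Mos at -0.08 and 1.19, and Malat1 had probes from -1.48 to -0.06. Trbv3, Gabra2, Ighv6-6 and Tcrb-V8.2 had probes past the threshold in both directions. In all, 13238 of 23040 probes passed the threshold (57.5%), 6266 higher and 6972 lower, and 14219 had an unadjusted p under 0.05. A mean of at least 0.5 in size was reached by 1479 higher and 1589 lower probes. Position of the spot in a repeat of 480 spots explained 36.7% of the variance of the mean ratio, against 1.87% for shuffled positions. With position removed, 12454 probes passed, of which 10117 were shared and had the same direction and 136 had the opposite one. At a mean of at least 0.5 in size, removal left 741 higher and 1350 lower probes. With no dye swap and a common reference RNA, a mean that is the same in all strains holds dye, reference and strain effects together.

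**Figure D1:**
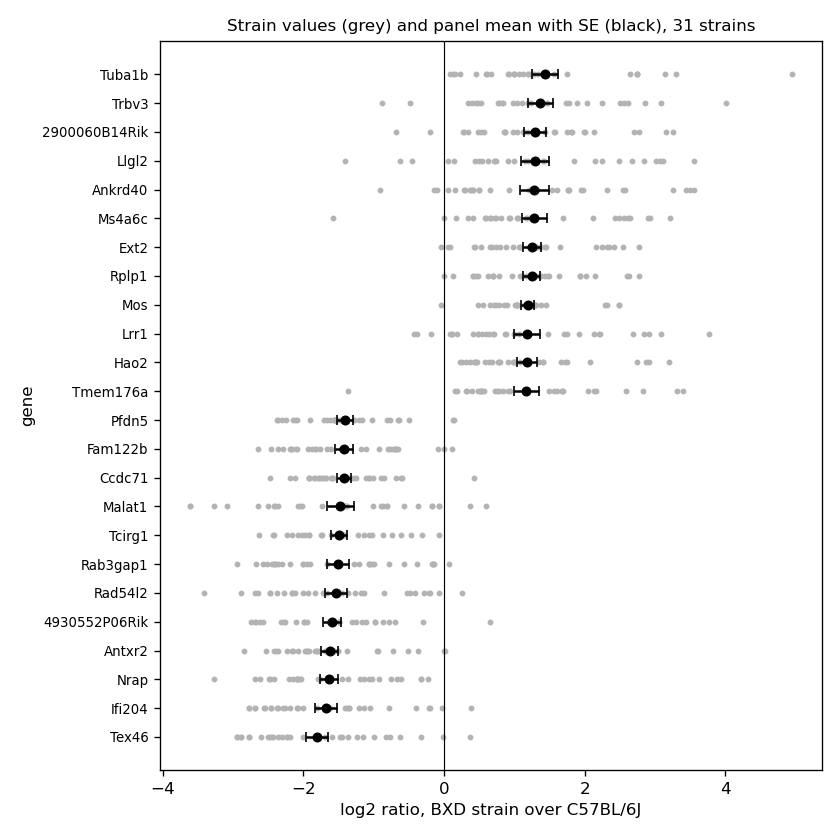
Log2 ratio of the BXD strain over C57BL/6J for the 12 highest and 12 lowest genes named by rule; grey points are the 31 strains and black points the panel mean with its SE. Tuba1b lies above 0 in all 31 strains, and Nrap and Tcirg1 lie below 0 in all of them.

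Genes known to differ between the parents were examined for the direction of the ratio, which their means cannot fix, since these also hold dye effects. Strain over reference, the limma convention, remains the likely reading, and every "higher" and "lower" rests on it. Nnt, Glo1, Alad and H2-Ea were fixed beforehand as the check of direction, each to be higher in the strains. Of these 4 genes only Nnt and Glo1 passed, and 2 did not. Nnt, the mitochondrial transhydrogenase gene disrupted in present-day C57BL/6J, was higher at 0.51 ± 0.0559 (adjusted p = 3.85e-09, 30 of 31 strains). Glo1, the glyoxalase gene duplicated in DBA/2J, was higher at 0.47 ± 0.0623 (adjusted p = 1.05e-07, 29 of 31 strains). Entpd4 was lower at -0.90 ± 0.110 (adjusted p = 2.90e-08) and so was Gpnmb, which carries a stop codon in DBA/2J, at -0.57 ± 0.123 (adjusted p = 1.77e-04). The complement gene Hc, defective in DBA/2J, was at -0.45 ± 0.0698 (adjusted p = 1.96e-06), and Klrd1, deleted in DBA/2J, at -0.33 ± 0.0601 (adjusted p = 2.09e-05). The mutations of Gpnmb and Klrd1 arose after BXD1-32 were bred. In BXD1-32 alone the means were -0.45 and -0.33, so the low means there are not effects of these mutations. Wdfy1 was higher at 0.20 ± 0.0532 (adjusted p = 0.00204), while Alad (0.11, adjusted p = 0.257), H2-Ea (-0.00, adjusted p = 0.990) and Tyrp1 (-0.06, adjusted p = 0.209) did not pass. None of these 10 genes had strain values in 2 clusters by the 1-sided simulation test, and the nearest was Gpnmb (adjusted p = 0.210). Of the sex-chromosome genes, the Y-linked Eif2s3y was higher at 0.52 ± 0.0570 (adjusted p = 2.94e-09) and the Y-linked Kdm5d lower at -0.61 ± 0.0960 (adjusted p = 2.54e-06), though all mice were male. Alad, Gpnmb, Entpd4 and H2-Ea followed the first principal component over strains (r = 0.829, -0.778, -0.734 and 0.580), as did Kdm5d (r = 0.738). Uty (-0.24, adjusted p = 0.142) and Xist (-0.08, adjusted p = 0.340) did not pass.

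Among gene lists against C57BL/6J, the cytosolic ribosome list was higher, with 16 of 20 genes up and 0 down both over all genes and adjusted over the list alone. Its mean log2 ratio was 0.60 (camera adjusted p = 1.43e-07; adjusted p = 0.244 with an estimated correlation), led by Rplp1 (1.25), Rpl27 (1.12), Rpl10a (1.10) and Rps6 (1.06). Oxidative phosphorylation had 18 of 22 genes higher by both adjustments and 0 lower, with a mean of 0.48 (camera adjusted p = 8.8e-06; adjusted p = 0.314 with an estimated correlation). Its leading members were Ndufa1 (1.04 ± 0.105) of complex I and the cytochrome oxidase genes Cox5a (1.00 ± 0.146) and Cox6c (0.90 ± 0.120). The proteasome list had 10 of 18 genes higher and 1 lower, 11 and 1 adjusted over the list alone, with a mean of 0.26 and the catalytic subunit genes Psmb7 (0.88), Psmb5 (0.82) and Psmb6 (0.79) at its top. Its camera adjusted p was 0.00205, and its adjusted p was 0.314 with an estimated correlation. Fatty acid oxidation had 11 of 15 genes higher and 1 lower by both adjustments (mean 0.26, camera adjusted p = 0.0125; adjusted p = 0.314 with an estimated correlation), with Cpt2 at 0.57 ± 0.0697 and Acadvl at 0.47 ± 0.0543.

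Adipose genes were higher in 6 of 9 cases by both adjustments (mean 0.31, camera adjusted p = 0.0228; adjusted p = 0.314 with an estimated correlation), among them the hormone-sensitive lipase gene Lipe (0.66 ± 0.0809) and Car3 (0.64 ± 0.0496). Skeletal muscle was the only called list that was lower, with 8 of 10 genes down by both adjustments and a mean of -0.28 (camera adjusted p = 0.0252; adjusted p = 0.244 with an estimated correlation). Acta1, skeletal muscle actin, was at -1.04 ± 0.147 and the troponin gene Tnnc2 at -0.50 ± 0.0552. The proximal tubule list had 8 of 17 genes higher and 1 lower, 10 and 2 adjusted over the list alone (mean 0.24, camera adjusted p = 0.0351; adjusted p = 0.393 with an estimated correlation). It was led by the endocytic receptor gene Lrp2 (0.67 ± 0.0819) and Cyp4b1 (0.60 ± 0.201). Cholesterol synthesis had 6 of 12 genes higher and 1 lower by both adjustments (mean 0.19, camera adjusted p = 0.0456; adjusted p = 0.314 with an estimated correlation), with the lanosterol demethylase gene Cyp51 at 1.01 ± 0.0757 and Idi1 at -0.38 ± 0.0677. These 8 lists were all that camera called among 29; with an estimated correlation 0 were called, fry called 20, and with spot position removed camera called 3.

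Lists not called by camera against C57BL/6J had adjusted p of 0.0573 for the unfolded protein response, 0.0752 for xenobiotic metabolism, 0.199 for heat shock, 0.248 for adrenal and interferon response genes, and 0.282 for antigen presentation and lymphocytes. The values were 0.376 for macrophages, 0.435 for endothelium, 0.547 for collecting duct, stroma and androgen-regulated genes, and 0.769 for podocytes, glia and liver. Genes known to differ between the parents had 0.877, neurons and immediate early genes 0.888, and pancreas, circadian clock and cell cycle genes 0.913. Lists of 4 measured genes each (loop of Henle, distal tubule, erythroid, genes for checking direction, mutations that arose after the first set, and sex chromosomes) had mean ratios of 0.04, 0.06, -0.13, 0.27, -0.16 and -0.10 and were not tested.

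The next comparison asked whether genes of 1 process or cell type rose and fell together over strains. Androgen-regulated genes had a mean pairwise correlation of 0.297 (adjusted p = 0.00207), with the alcohol dehydrogenase gene Adh1 (0.684 with the rest of the list), the ornithine decarboxylase gene Odc1 (0.579) and the anion transporter gene Slco1a1 at its centre. The mean of this list ran from -0.96 in BXD33 to 1.33 in BXD2. Proximal tubule genes had 0.235, with Cyp4b1 (0.747), the urate transporter gene Slc22a12 (0.744) and the organic anion transporter gene Slc22a6 (0.737) tracking the list, whereas Fbp1 (-0.536) and Slc6a19 (-0.317) ran against it, 2 genes chosen after their values were seen. The list mean ran from -0.77 in BXD38 to 1.20 in BXD2, and Cyp4b1 alone from -2.88 in BXD38 to 3.32 in BXD2. Oxidative phosphorylation had 0.285, led by Ndufb8 (0.825) and Cox5b (0.813), and ran from -0.48 in BXD15 to 1.13 in BXD12. Endothelium had 0.273, with the receptor genes Tek (0.697) and Kdr (0.654), while Cdh5 (-0.0840) and Tie1 (0.00874) did not follow, again chosen after their values were seen. The ribosome list had 0.245, led by Rpl10a and Rps6 (0.801 each), the proteasome list 0.170, led by Psma7 (0.643), and fatty acid oxidation 0.164, led by the receptor gene Ppara (0.721). For the 6 lists other than the androgen-regulated one named so far, p was 0.0001, the smallest that 10000 random lists can give, and the adjusted p was 0.000483.

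Adipose genes correlated at 0.222 (adjusted p = 0.00217), led by the fatty acid binding protein gene Fabp4 (0.679) and Ucp1 (0.647). Cholesterol synthesis genes correlated at 0.124 (adjusted p = 0.0190), led by Cyp51 (0.715), and antigen presentation genes at 0.0864 (adjusted p = 0.0200), led by the class II gene H2-Aa (0.787). Some of these calls depended on the setting. Adipose fell to 0.0442 (adjusted p = 0.238) with the first principal component removed, antigen presentation to 0.0619 (adjusted p = 0.0600) with Spearman correlation and to 0.0667 (adjusted p = 0.0560) with the probe of largest spread, and cholesterol synthesis to 0.0945 (adjusted p = 0.0505) without BXD15 and BXD38. Removal of spot position kept all 10 calls but lowered the proteasome list to 0.0646 (adjusted p = 0.0368), endothelium to 0.155 (adjusted p = 0.0141) and the ribosome to 0.163. Of the 10 called lists, 7 had their lowest mean in BXD15, where Gapdh was also at its lowest (-1.20). Heat shock came closest among the other 19 lists at 0.122 (adjusted p = 0.0662). Glia had 0.0472 (adjusted p = 0.227), neurons -0.00104 (adjusted p = 0.522) and podocytes -0.0157 (adjusted p = 0.557). Within array cluster 1 the mean correlation of the androgen-regulated list was 0.229, within cluster 4 -0.151 and within cluster 5 0.336. For the proximal tubule list the values were 0.261, 0.180 and 0.0815, for oxidative phosphorylation 0.292, 0.146 and 0.178, for the ribosome 0.241, 0.0826 and 0.282, and for endothelium 0.180, 0.10 and 0.135. The proteasome list had 0.137, 0.0918 and 0.0991, fatty acid oxidation 0.0392, 0.120 and 0.0643, adipose 0.130, 0.122 and 0.0254, cholesterol synthesis 0.147, 0.0368 and 0.0627, and antigen presentation 0.149, -0.0378 and 0.00844. Within clusters 1, 4 and 5, 9, 3 and 4 lists passed the permutation test. Only oxidative phosphorylation passed in all 3, with adjusted p of 0.000967, 0.0280 and 0.00145.

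**Figure D2:**
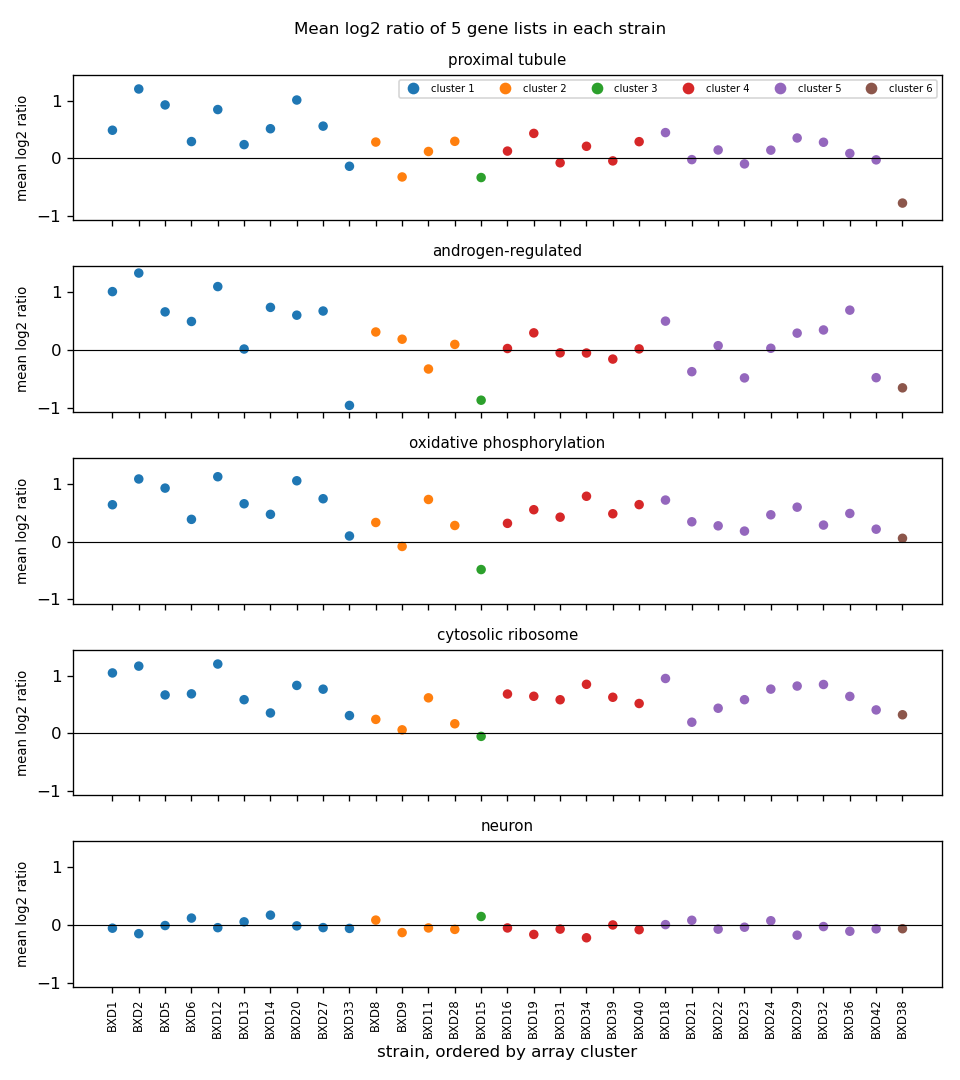
Mean log2 ratio of 5 gene lists in each of the 31 strains, ordered and coloured by array cluster. The proximal tubule list runs from -0.77 in BXD38 to 1.20 in BXD2, and the neuron list stays near 0.

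In recombinant inbred strains a gene with a strong local effect has strain values in 2 clusters, and this was sought probe by probe. Tmem134 had the widest distance between cluster medians, 2.75, with 14 strains from -2.67 to -0.90 and 17 from -0.55 to 1.01. Thsd1, which encodes a thrombospondin-domain membrane protein, had 14 strains from -3.41 to -1.49 and 17 from -0.86 to 0.24, a distance of 2.33. Eps15, an endocytic adaptor gene, had 13 strains from -2.29 to -1.33 and 18 from -0.65 to 0.52. For 4930402F06Rik, 6 strains lay between -2.25 and -1.69 and 25 between -0.54 and 0.41. For 1 of the 34 probes of Ighv6-6, an immunoglobulin gene, 16 strains lay between -0.09 and 0.47 and 15 between 0.98 and 1.51, and the split removed 91.3% of its sum of squares. In total 37 probes passed the threshold, 27 of them with 1 gene name, and 1601 (6.95%) had an unadjusted p under 0.05. The count depended on the simulation: it was 8 to 70 in 10 runs with other random numbers and 44 with 5000000 simulated samples, which kept all 37. The dip statistic called 0 probes, with 141 at an unadjusted p under 0.05.

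Others named by distance of medians were Ttyh3 (2.23), 4930597O21Rik (2.08), the granzyme gene Gzmc (2.00), Enpp3 (1.99), the kallikrein gene Klk1b24 (1.92), the lysosomal peptidase gene Tpp1 (1.92), the adducin gene Add2 (1.81) and Olfr68 (1.64). Below these came Nt5c1b (1.62), 4931439C15Rik (1.58), Lrrc6 (1.58), 1700052I22Rik (1.56), 9330198N18Rik (1.53), Vsig10l (1.45), the myosin gene Myh10 (1.14), Cdk6 (1.10), Xpot (0.97), Spns2 (0.94) and Lgalsl (0.75), and Eps15 and Ighv6-6 had 2.16 and 0.94. Many of these genes shared their pattern over strains. Probes of genes on different chromosomes had a median absolute correlation of 0.542, against 0.237 for random probes of matching spread (1-sided permutation p = 0.001, the smallest that 1000 draws can give). The first principal component had an absolute correlation over 0.5 with 29 of the 37 probes, whereas 4930402F06Rik (0.00120) and 9330198N18Rik (0.00515) had almost none. With the first principal component removed, 0 probes passed with 100000 simulated samples, where 2 probes were at the smallest p and at least 5 are needed there to pass. With 5000000 samples, chosen after seeing the data, 4930402F06Rik and Ptgdr2 passed, the latter not among the 37. Removal also lowered the share of simulated clusters recovered, to 18% at 4 SD and 74% at 6 SD.

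Neighbouring genes were compared because strains inherit chromosomes in long blocks. Tial1, an RNA-binding protein gene, and its neighbour Bag3, a chaperone regulator gene, had the strongest correlation over strains (Pearson r = 0.911, Spearman rho = 0.908, both with permutation p = 1e-05, the smallest the permutations can give). Over 14604 adjacent pairs the adjusted p was 0.0460. Without BXD5 and BXD11, the strains farthest from the median of Tial1, r was 0.913, and within array clusters 1, 4 and 5 it was 0.815, 0.911 and 0.880. The antitrypsin genes Serpina1a and Serpina1c had r = 0.899 and rho = 0.907 (permutation p = 1e-05 each, adjusted p = 0.0460), r = 0.881 without BXD12 and BXD2, farthest from the median of Serpina1a, and r of 0.927, 0.903 and 0.892 within the clusters. They belong to 1 gene family, whose probes can bind each other's transcripts. Pairs short of the threshold included Cndp2 and Cyb5a (r = 0.883, adjusted p = 0.0713), App and Adamts1 (r = -0.873, adjusted p = 0.0812), Cyp2a12 and Cyp2f2 (r = 0.843, adjusted p = 0.199) and Mmp8 and Mmp20. The last pair had r = 0.824 and rho = 0.290, and r = 0.163 without BXD6 and BXD18, so it rests on those strains. The remaining named pairs were 3110009F21Rik and Ppp2r5c (0.814), Padi1 and 4930515B02Rik (-0.803), Clasp2 and Ubp1 (0.793), and Ighv9-4 and Ighv6-6 (0.792). Within array clusters 1, 4 and 5, r was 0.482, 0.733 and 0.0518 for 3110009F21Rik and Ppp2r5c and 0.719, -0.0357 and 0.701 for Ighv9-4 and Ighv6-6. It was -0.617, -0.868 and -0.602 for Padi1 and 4930515B02Rik and 0.920, 0.598 and 0.881 for Clasp2 and Ubp1. Over all pairs the mean absolute correlation was 0.215, against 0.211 after shuffling, an excess of 0.00388 (1-sided permutation p = 0.003). Without gene families the excess was 0.00272 (permutation p = 0.013). Long blocks would give an excess between genes farther apart as well. For genes 2 and 5 apart, compared after the results were seen, it was 0.000845 (permutation p = 0.239) and 3.15e-05. An excess beyond adjacent genes was thus not established.

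**Figure D3:**
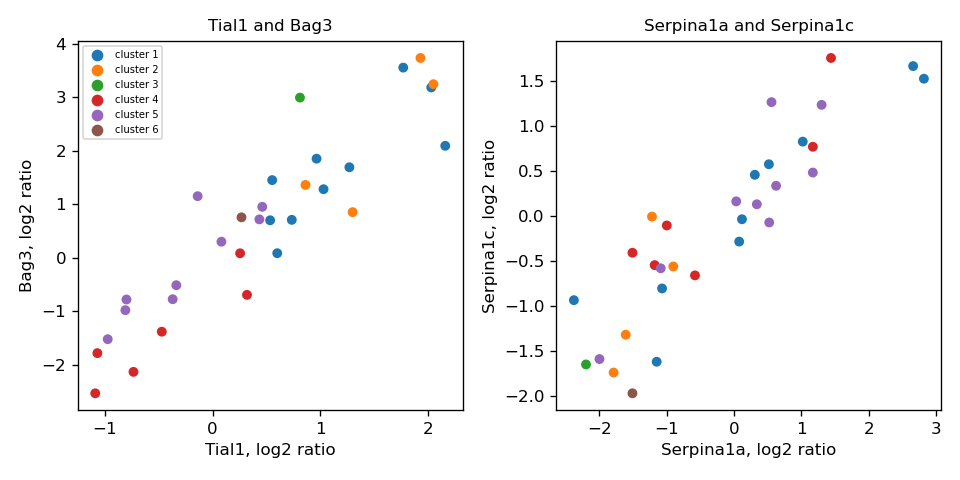
Log2 ratios of Tial1 and Bag3 and of Serpina1a and Serpina1c in the 31 strains, 1 point per strain, coloured by array cluster. Pearson r is 0.911 for Tial1 with Bag3 and 0.899 for Serpina1a with Serpina1c.

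The last comparison asked whether strains BXD33-42 differed from BXD1-32. Sema6a, which encodes a semaphorin, was lower in BXD33-42 by a log2 difference of -0.71 ± 0.123 (SE, n = 7 and 24, limma adjusted p = 0.0217). Its values were -1.27 to -0.04 in BXD33-42 and -0.36 to 0.52 in BXD1-32. A probe without a gene name was lower by -1.14 ± 0.191 (limma adjusted p = 0.0217). Neither passed without BXD36 or without BXD39, where 0 probes passed, and 33 probes passed without BXD33. Within array clusters 1, 4 and 5 the difference of Sema6a was -1.31, -0.51 and -0.43, and that of the unnamed probe -1.01, -1.05 and -1.24, with 1, 3 and 2 arrays of BXD33-42. Ap1b1 (-0.95 ± 0.187, adjusted p = 0.0982), Gtf2e1 (0.93 ± 0.191), Agfg1 (-0.80 ± 0.165) and Tcrb-V8.2 (-0.77 ± 0.159) did not pass. By limma 2904 probes had an unadjusted p under 0.05. With array cluster as a block, 0 probes passed and 2266 had an unadjusted p under 0.05. Camera called 0 lists, and the lowest adjusted p was that of the proximal tubule list (mean -0.38, adjusted p = 0.175; adjusted p = 0.911 with an estimated correlation), with 0 genes lower over all genes and 2 adjusted over the list alone. Androgen-regulated genes had a mean difference of -0.51 (camera adjusted p = 0.211; adjusted p = 0.911 with an estimated correlation). Of the genes whose mutations arose in the parents between the breedings, Gpnmb differed by -0.54 ± 0.280, Nnt by 0.02 ± 0.135, Klrd1 by -0.02 ± 0.145 and Gabra2 by 0.14 ± 0.173. None passed in limma, and their lowest p was 0.416 adjusted over all genes and 0.246 adjusted over the list alone.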

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

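The counts over other splits of the strains, the kidney lists one by one and under other settings, the tests of spot position and of mutations in the parents, the proteasome test and the comparison of kidney with brain lists were chosen after the results were seen. The regression of the proximal tubule list on the ribosome list and the test of the share of proximal tubule were stated before their results.

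In the 7 arrays of BXD33-42, 158 results were examined for a strain far from the other 6, and 14 were found. Chance gives about 5% of such results for normal values. Eps15, 4930597O21Rik, 4931439C15Rik, Ighv6-6 and Spns2 were named for strain values in 2 clusters. A lone array can follow from that choice, so 5% is not their chance level. Cyp4b1, Slc22a6, H2-Aa, Rps6, Rps14 and 4930515B02Rik were also chosen from these data, for correlation with a list or a neighbour. Cyp4b1 and Slc22a6 are part of the proximal tubule mean, so these 3 results overlap. The 14 of 158 can thus not be set against 5%. Of the 14 results, 6 came from BXD33, which is the only BXD33-42 array in array cluster 1. In BXD33, Eps15 was at -0.041 (others -2.27 to -1.33), 4931439C15Rik at 0.50 (others -2.30 to -1.12), Ighv6-6 at -0.00304 (others 1.00 to 1.24), Spns2 at 0.20 (others 1.09 to 1.49), 4930515B02Rik at -2.05 (others -0.30 to 0.40) and H2-Aa at 0.34 (others -1.09 to -0.48). In BXD38, Cyp4b1 was at -2.88 (others -0.64 to 0.72), Slc22a6 at -1.17 (others -0.35 to 0.20) and the proximal tubule mean at -0.77 (others -0.14 to 0.29). In BXD42, 4930597O21Rik was at -2.14 (others -0.26 to 0.60) and the lymphocyte mean at 0.12 (others -0.38 to -0.18). Single strains stood apart for 1 of the 2 probes of Gabra2 (-2.02 in BXD40, others -0.39 to 0.52), Rps6 (1.91 in BXD36, others 0.38 to 0.97) and Rps14 (1.46 in BXD34, others 0.35 to 0.76). The other probe of Gabra2 had BXD40 at -0.15, within the range of the others (-0.58 to 0.47).

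Between BXD33-42 and BXD1-32, Sema6a differed by -0.71 and the unnamed probe by -1.14. Of 100 splits of the arrays into groups of 24 and 7, 5 gave at least the 2 probes of the real one (highest other 11), so chance could not be excluded for that count. For probes at an unadjusted p under 0.05, 4 of 100 splits, the real one included, gave as many as the real 2904 (highest other 3530), a share close to the threshold of 0.05. Among 100 splits that kept the number of BXD33-42 arrays in each array cluster, only 1, the real one, gave as many (highest other 2459), and with array cluster as a block the real 2266 was also the only one, by a narrow margin (highest other 2250). Each of these splits left BXD38 in BXD33-42 and BXD15 in BXD1-32, because each stood alone in its cluster. They could thus not test whether the count of 2904 rests on these arrays, and chance was not excluded for it. With array cluster as a block, each of these lone arrays is fitted exactly, so the count of 2266 does not rest on them. That count argues against chance only by the narrow margin given, in a test chosen after the results were seen. Without the block, the count was 1917 without BXD38 and 2048 without BXD15 and BXD38. It was 2225 with position removed and 1506 with 3 components as covariates. These counts were not set against splits. For gene lists the real count of 0 was reached by 100 of 100 splits (highest other 8), which decides nothing, since no split can give fewer. The split with 11 probes may reflect a structure of the arrays, which was not tested. Mutations that arose in the parents between the breedings could add differences, but the lowest p of the 4 genes was 0.246 adjusted over the list alone and the interval of Gpnmb, -1.11 to 0.03, leaves this open.

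The covariation of the proximal tubule list, lowest in BXD38, could stem from spot position, from a shift shared by abundant transcripts, or from more or less proximal tubule in the tissue. Position was argued against as the whole cause, since 10 lists stayed past the threshold after its removal, this one at 0.213. After regression on the ribosome list, the mean correlation of this list fell from 0.235 to 0.137 (random lists up to 0.0485 at their 95th percentile). The proteasome list fell to 0.0376 (95th percentile 0.0442), as a shift of abundant transcripts predicts. The proximal tubule mean itself correlated with the ribosome mean (r = 0.669). The value of 0.137 argues only against the part of such a shift that the ribosome mean captures as the whole cause. A shift that this mean captures incompletely stays open. More or less proximal tubule as the whole cause predicts opposite moves of other kidney lists, but the median correlation with podocyte, collecting duct, endothelium and stroma lists was 0.437 (permutation p = 0.005; single lists -0.274, 0.682, 0.529 and 0.345), and still 0.411 with position removed and 0.375 with the ribosome mean regressed out (permutation p = 0.0056 and 0.0154), although only endothelium covaried among its own genes, which makes the other means weak measures of their cells. Differences between strains in the activity of these genes, which the design allows, remain open and were not tested.

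The conflict between kidney in the titles and whole brain in the source fields was tested with gene lists. If the RNA came from kidney, proximal tubule genes should covary over strains and neuron and glia genes should not. The mean correlation was 0.235 for proximal tubule, above the 95th percentile of random lists (0.0466), and -0.00104 for neurons and 0.0472 for glia, below theirs. Podocyte (-0.0157) and collecting duct (0.0344) genes, which are also of kidney, did not covary either, so the neuron and glia values do not separate brain from kidney. The proximal tubule value is consistent with kidney RNA but does not exclude brain, and ratios to a reference do not show the absolute level of any transcript.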

How the results depend on the processing

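Removal of spot position or 3 components, array clusters, leaving out BXD15 and BXD38, and other random numbers were chosen after seeing the data. Repeating the quantile normalization changed nothing by construction, since the columns already had identical sorted values, and centring shifted all values by 0.0127. The panel mean kept within 1.5 times its count except with treat, which tests against 0.2 and called 4791; without each strain in turn it was 12931 to 13483. Named panel-mean, parental-difference and sex-chromosome probes kept their call in 1477 results, with 2 stronger and 2 weaker. Direction was checked only for probes called in the main fit. For BXD33-42 against BXD1-32, probes numbered 116 with array weights, 0 with the first component, 3 components or array cluster as a block, 1 with position removed, 1 without BXD15 and BXD38, and 298, 0 and 1 within clusters 1, 4 and 5; cluster 1 has 1 BXD33-42 array, assumed to vary like the others. Without single strains they were 0 to 33: 33 without BXD33, 4 without BXD16 or BXD34, 1 without BXD38, and 0 without BXD36 or BXD39. Lists in that comparison were 0 to 2, the 2 without BXD36. Probes with 2 clusters numbered 311 with a t null and 0 with the dip statistic. They also numbered 0 with the first component, 3 components or cluster means removed, where fewer than 5 probes at the smallest p cannot pass. With 5000000 samples they were 2, 0 and 0 after these removals. Removal of 3 components left only 3% and 34% of simulated clusters at 4 and 6 SD recovered, in simulated values without the structure of the arrays. Other random numbers gave 70, 60 and 8 in 3 of 10 runs. Without single strains they were 9 (BXD20) to 33, under a shared simulation of 100000 samples, with 29 of 31 beyond 1.5 times; with 1000000 samples they were 19 to 52. Named 2-cluster probes stayed past the threshold in 441 results and lost it in 567. Covarying lists numbered 9, 3 and 4 within clusters 1, 4 and 5, which hold 10, 6 and 9 arrays, and 9 to 11 without single strains. Within cluster 4 the mean correlation reversed to -0.151 for androgen-regulated and -0.0378 for antigen presentation genes. Lists against C57BL/6J numbered 0 with an estimated correlation, 20 with fry, 3 with position removed (ribosome, oxidative phosphorylation and skeletal muscle) and 6 to 9 without single strains. The neighbour excess was 0.0258 (permutation p = 0.342) among 2-cluster genes, with 13 pairs, and 0.00337 to 0.00453 without single strains. Some settings had fewer arrays, fewer pairs or a different null, and the causes of the changes were not tested. No paired analysis was possible because the replicate numbers follow the order of deposit and pair no arrays. Signal over background is unknown, so its limit on weak spots could not be assessed.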

Other observations

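All tests here were chosen after the results were seen, except the neighbour excess for genes 1 apart. For the probes with strain values in 2 clusters, separate loci and a structure of the arrays were considered as origins. Separate loci predict little correlation between genes on different chromosomes, and the median absolute correlation of 0.542 was above the highest of 1000 random draws (0.394), which argues against separate loci for these probes as a set. A structure of the arrays shared by many probes predicts a high value. Any other factor shared by these genes, such as 1 locus acting on many of them, predicts it too. The value cannot tell these apart. A local effect on single genes such as 4930402F06Rik, whose correlation with the first principal component was 0.00120, stays open and was not tested, since no genotypes were used here.

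The mean log2 ratio was away from 0 in 57.5% of the probes. Spot position, a gene-specific dye effect, the common reference RNA or the strains could each contribute. Position as the whole cause is argued against by the 12454 probes still past the threshold after its removal. A dye effect cannot be told apart from a difference shared by the strains, because 0 arrays were dye-swapped. Nor can an effect of the reference RNA, which was common to all arrays. A single local allele, carried by only part of the strains, would leave the other strains near 0. Of called probes with 1 gene name, 1353 higher and 954 lower had the same sign in at least 28 strains. For these probes such an allele is argued against as the whole cause. Differences between the BXD strains and C57BL/6J remain among the open explanations.

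Of 479 gene families defined by shared symbols, 25 covaried past the threshold, 20 did so with array cluster means removed, and 13 did both. The complex I family Ndufb (9 genes) had mean correlations of 0.311 and 0.430, and the Rpl family (43 genes) 0.226 and 0.212. The lipoxygenase family Alox fell from 0.349 to 0.10. Within array clusters, the mean of the androgen-regulated list correlated best with Mogat1, an acyltransferase gene (r = 0.863, familywise permutation p = 0.003), followed by Ugt2b5 (r = 0.809, familywise permutation p = 0.064). The proximal tubule mean correlated best with Tmem176a (r = 0.891, familywise permutation p = 0.001, the smallest the permutations can give). Psmb7 (r = 0.846), Oaz1 (r = 0.844), the brush-border protease gene Mep1a (r = 0.843), Rps10 (r = 0.841) and Naca (r = 0.827) followed. Excess correlation without gene families was 0.00283 for genes 1 apart (permutation p = 0.0149), 0.000845 for genes 2 apart (permutation p = 0.239) and 3.15e-05 for genes 5 apart. The value for genes 1 apart repeats, with other shuffles, the alternative fixed at the start (0.00272, permutation p = 0.013).

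The means of the 10 called lists were compared with the mean of the 232 Gapdh spots over the 31 strains. Pearson r was 0.273 to 0.587 (permutation p adjusted over the 10 lists 0.0085 to 0.148) and Spearman rho 0.113 to 0.542 (adjusted permutation p 0.0230 to 0.547). Without BXD15 and BXD2, farthest from the Gapdh median, r was -0.00962 to 0.634. With array cluster means removed it was -0.309 to 0.291 (adjusted permutation p 0.741 to 0.812). Within array clusters 1, 4 and 5 it ran from -0.576 to 0.593, from -0.797 to 0.731 and from -0.163 to 0.533.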
